A study of Mus musculus with 8 samples.

How the data were processed

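The series holds 8 RNA-seq libraries of a TGF-β treated mouse kidney line, 4 labelled ad-GFP and 4 labelled ad-CRE. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA-seq kit. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool, the gene annotation and the authors' test are not given in the sources used here, nor is it given whether strand was used, so reads of overlapping genes on opposite strands may be counted together.

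The authors deposited 1 table of 22274 genes. Per the file headers, it holds a read count and an FPKM value (a count scaled by gene length and library size) for each library. It also holds the authors' mean FPKM per group, the authors' log2 fold change, which equals the log2 ratio of these means, and the authors' p-value and FDR. The deposited counts are whole numbers with totals of 15998257 to 22297598 per library. In 38 genes every count is 0 while an FPKM is above 0, so the deposited counts may be rounded estimates. A total of 3965 genes had 0 counts in every library. Of the gene IDs, 22219 (99.75%) were found in GENCODE release M21 for GRCm38, which gave the coordinates, and 97.86% of those are protein-coding. The deposited FPKM values have 2 decimals and were used only in alternative settings.

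Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood test (glmQLFit, glmQLFTest) with the group as the only term. P-values were adjusted by Benjamini-Hochberg over all 13702 genes tested, with a threshold of 0.05. CPM values are counts scaled to the library size after TMM factors. The SE of a log2 fold change is its size divided by the square root of the F statistic. A group is said not to overlap the other when each of its libraries lies on one side of every library of the other group. Pairs of replicates of 1 group differed by more than sampling noise (chi-square per degree of freedom of 1.71 to 3.24), so none was treated as a copy of another. Separate library preparations of 1 culture could differ by as much, so this does not show that the replicates were separate cultures.

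The gene lists, 18 of processes and 6 of cell type markers, were written from general knowledge together with the rule for named genes, the test, the design and the alternatives. Lists of at least 5 tested genes were compared with the other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over 23 lists. The camera test with a correlation estimated from the residuals of each list and the fry test were alternatives. With DESeq2 the lists were tested by cameraPR, a form of camera that takes the test statistics of the genes instead of log-CPM values. List results with DESeq2 therefore differ from the main ones in the set test as well as in the fit. Named genes are Suv39h1 and Cxcl10, the 10 largest rises and 10 largest falls, and members of each list. The rises and falls were taken among genes past the threshold with a mean log2 CPM of at least 2, groups that do not overlap and a symbol that is not a placeholder. In each list the members named come from the 4 with the smallest p-values and the 2 with the highest mean expression. Some genes that this rule takes are not reported here. Other genes are said to be singled out after their values were seen.

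The alternatives were scaling by DESeq2 size factors or by total counts only, no filter beyond 1 read, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, a term for the replicate number, and leaving out each library in turn. On simulated counts for 13599 genes with 200 changed, the edgeR test recovered 64%, 84%, 92% and 100% of genes changed by 0.25, 0.5, 1 and 2 log2 units for this comparison of 4 against 4 libraries. Of its calls there 7.61% were false, and camera found the changed list and called 0 of 23 unchanged ones. The genes were simulated independently of one another, so this does not test camera where the members of a list move together. Far fewer genes were changed there than were called in the real libraries. Figures were drawn with matplotlib 3.10.9. Each per-library column of the table was matched to a sample by its title, and the annotation columns served only for symbols, pathways and transcription factor families.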

Results

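Gene expression was measured by RNA sequencing in 8 libraries of a mouse kidney line labelled RFB, given as fibroblasts, all treated with TGF-β, a cytokine that drives fibroblasts to make matrix. In 4 libraries the cells had received an adenovirus labelled GFP (ad-GFP) and in 4 an adenovirus labelled Cre (ad-CRE), the recombinase that removes DNA lying between loxP sites. The series title and design text name Suv39h1, an enzyme that places methyl groups on lysine 9 of histone H3, as the gene targeted in these cells, and the title also names the chemokine CXCL10. The labels used here do not describe the allele on which Cre was to act. Total counts per library were 20920828, 19396350, 17186314 and 15998257 in ad-GFP replicates 1 to 4, and 22297598, 19388349, 21839459 and 17572152 in ad-CRE replicates 1 to 4. At least 1 count was found for 16359 to 16648 genes in the ad-GFP and 15911 to 16169 genes in the ad-CRE libraries, and genes of the mitochondrial chromosome took 6.46% to 6.60% and 7.20% to 7.42% of counts, with no overlap between groups in either measure. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

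The targeted gene was examined first in every library. Suv39h1 (ENSMUSG00000039231, GRCm38 chromosome X, 8061171 to 8074760, minus strand, protein-coding) had 37.2, 43.6, 44.1 and 41.3 CPM (counts scaled to library size) in ad-GFP replicates 1 to 4, and 32.3, 32.9, 33.4 and 31.6 CPM in ad-CRE replicates 1 to 4. It fell in the ad-CRE group to 0.785 of the ad-GFP level, from 41.5 ± 3.16 to 32.5 ± 0.795 CPM (mean ± SD, n = 4 each), with no overlap between groups. The log2 fold change was −0.35 (SE 0.053, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.65e-07). The gene totals rest on 3069 reads in the ad-GFP and 2616 reads in the ad-CRE libraries, and do not show which exons the reads came from. A far larger fall was seen in Smarca4, a gene singled out after its values were seen, which encodes BRG1, an ATPase of SWI/SNF chromatin remodelling complexes (ENSMUSG00000032187, chromosome 9, 21616169 to 21704230, plus strand). Its level was 288 ± 11.1 CPM in ad-GFP and 34.3 ± 3.2 CPM in ad-CRE (SD, n = 4), 8.40-fold lower, with a log2 fold change of −3.07 (SE 0.044, edgeR adjusted p = 3.82e-31).

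**Figure D1:**
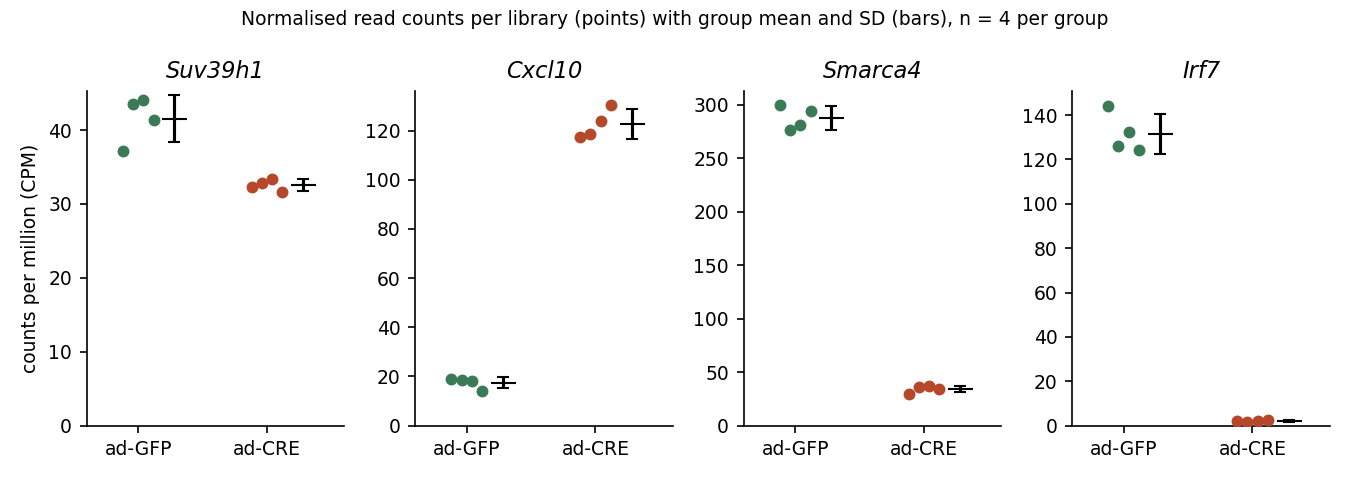
Normalised read counts (CPM, linear axes from 0) of Suv39h1, Cxcl10, Smarca4 and Irf7 in each of the 4 ad-GFP and 4 ad-CRE libraries, with one point per library and bars for the group mean and SD. Suv39h1 lay between 37.2 and 44.1 CPM in ad-GFP and between 31.6 and 33.4 CPM in ad-CRE, whereas Smarca4 lay between 276 and 300 CPM in ad-GFP and between 29.9 and 37.3 CPM in ad-CRE.

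Cxcl10, the chemokine of the title and a ligand of the receptor CXCR3, rose 6.98-fold in ad-CRE (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand). It was at 17.4 ± 2.27 CPM in ad-GFP and 123 ± 5.93 CPM in ad-CRE (SD, n = 4), a log2 fold change of 2.80 (SE 0.057, edgeR adjusted p = 1.8e-27), and every ad-CRE library lay above every ad-GFP library. Its neighbour Cxcl11, a gene for another CXCR3 ligand, rose by a log2 fold change of 3.67 from a low level, 0.496 to 6.59 CPM. GENCODE M21 types Cxcl11 as a polymorphic pseudogene, a gene intact only in some individuals. These reads therefore do not show that a working ligand was made. Ppbp (1.54) and Cxcl16 (0.71) rose as well. Of the 22 chemokine genes tested, 8 rose, 6 fell and 8 did not pass. As a list the chemokines did not stand apart from other genes (median log2 fold change 0.02, camera adjusted p = 0.516), and the sign of the median was not stable: it was −0.15 with no filter beyond 1 read, 0.84 with the stricter filter and −0.08 to 0.21 when 1 library was left out, below 0 without ad-GFP replicate 1, ad-GFP replicate 4 or ad-CRE replicate 3. Among 34 genes of NF-kB signalling and inflammatory cytokines, 20 rose, 9 fell and 5 did not pass (median 0.35, camera adjusted p = 0.0762). Nfkbia, the inhibitor of NF-kB, rose by 1.73 and Nfkb1 by 0.72, whereas Ptgs2, the inducible cyclooxygenase, had a log2 fold change of −2.27 and Il1rn, the interleukin 1 receptor antagonist, of −2.50. Tnfaip3 rose by 0.27 in counts, but did not pass on the log2(FPKM + 1) scale (−0.022) or the log2(FPKM + 0.1) scale (−0.023).

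Across the 13702 genes tested, 10022 (73.1%) passed the threshold, of which 5047 rose and 4975 fell in ad-CRE. Which direction held more genes turned with the scaling, with 4734 that rose and 5287 that fell when libraries were scaled by total counts only. A change of at least 1 log2 unit was seen in 1955 genes, 663 that rose and 1292 that fell. The groups did not overlap in 66.2% of genes tested, where chance gives 2.86%. The replicates varied little, with a common biological coefficient of variation of 0.032, so that small differences passed. Among genes with a mean log2 CPM of at least 2, the largest rise was that of Cemip, which encodes a hyaluronan-binding protein, from 2.25 ± 0.378 to 43.6 ± 3.23 CPM (SD, n = 4), a log2 fold change of 4.27. It was followed by Vgf (3.47), a secreted neuropeptide precursor, Tmem130 (3.09), Prom2 (3.07), the ion channel gene Hcn3 (3.04), Soga3 (3.01), Ube2ql1 (2.95), the serine protease Prss22 (2.81), Cxcl10 and Npl (2.57). The largest edgeR adjusted p among these 10 was 2.31e-16, for Tmem130.

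The 10 largest falls, taken with the same limit on mean expression, were led by genes of the interferon response. Oas2 and Oas3, which encode sensors of double-stranded RNA, had log2 fold changes of −7.17 and −7.06, Ifi44 of −6.19, the interferon-inducible GTPases Tgtp1 and Iigp1 of −6.20 and −6.18, and Mx2 of −5.99. Apol9a (−6.94), Apol9b (−6.05), the class I histocompatibility gene H2-Q5 (−6.00) and the glutathione transferase Gsta1 (−6.05) completed them. GENCODE M21 types H2-Q5 and Mx2 as polymorphic pseudogenes. The ad-CRE levels rest on few reads, 22 in all for Oas2 against 3004 in ad-GFP, and Oas2 had −7.47 to −6.78 when 1 library was left out. The log2(FPKM + 1) scale, on which the added 1 shrinks the change of low genes, gave −3.42, whereas the ratio of mean FPKM in the authors' deposited table gave −6.79. Tgtp1, Apol9a, Apol9b, Gsta1 and the H2-Q genes have near-identical relatives, and the treatment of shared reads is not given in the sources used here, so their single values are uncertain.

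**Figure D2:**
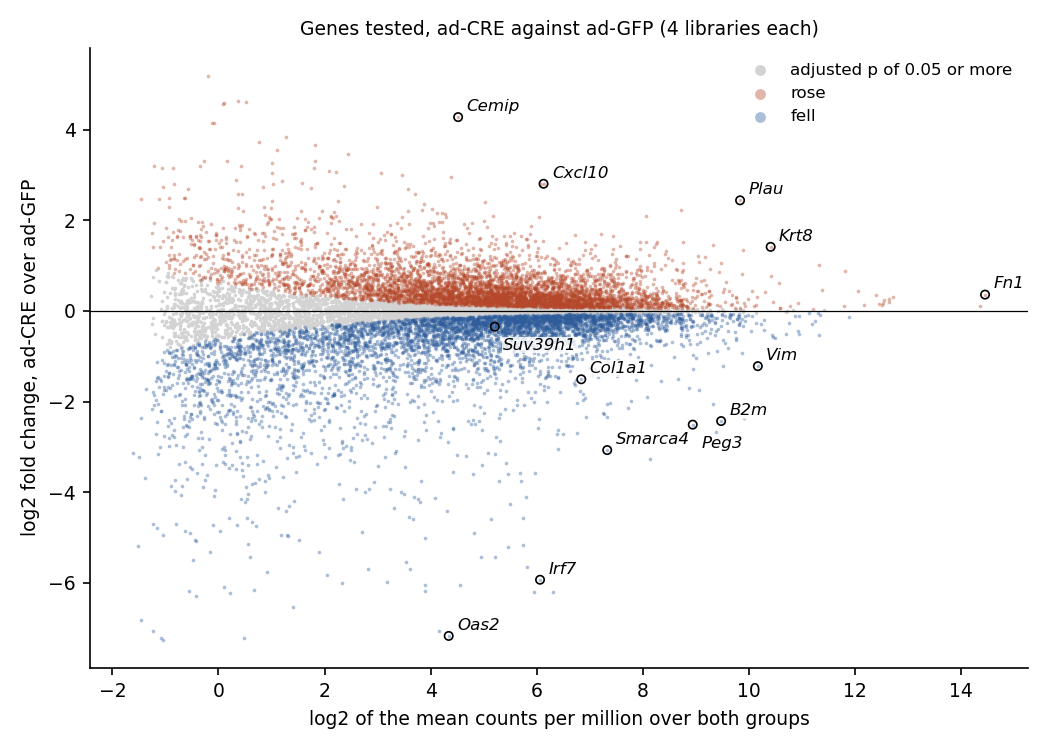
Log2 fold change (ad-CRE over ad-GFP) against the log2 of the mean CPM over both groups for the 13702 genes tested, with genes that rose, fell or did not pass in separate colours and genes named in the text circled. Cemip and Cxcl10 lie at 4.27 and 2.80, Oas2 and Irf7 at −7.17 and −5.93, and Suv39h1 at −0.35.

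Interferon-stimulated genes formed the group with the largest fall. Of 51 tested, 49 fell, 0 rose and 2 did not pass, with a median log2 fold change of −2.83 (camera adjusted p = 2.63e-19, adjusted p = 0.0663 with an estimated correlation). Irf7, a transcription factor of the type I interferon response, went from 132 ± 8.95 to 2.17 ± 0.316 CPM (SD, n = 4; log2 fold change −5.93, edgeR adjusted p = 2.54e-32). Isg15, a ubiquitin-like modifier, had −5.16 and Bst2, also called tetherin, −3.04. Genes of class I antigen presentation fell with them, 22 of 22 tested, with a median of −1.21 (camera adjusted p = 1.01e-08, adjusted p = 0.0663 with an estimated correlation). B2m, the invariant chain of class I molecules, had −2.43, H2-D1 −1.75, and H2-Q6 −5.66, whereas the chaperone Calr had −0.10. Cxcl10 and Cxcl11, which interferon also induces, rose in the same libraries. Leukocyte and macrophage markers also fell beside these groups, 15 of 22 tested, with a smaller median of −0.34.

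For the gene lists fixed before the data were examined, the counts adjusted over the list alone were the same as those over all genes in 20 of 24 lists. The other 4 differed by 1 gene each: adjusted over the list alone, 35 cell cycle genes fell rather than 34, 18 stress response genes fell rather than 17, 19 immediate early genes rose rather than 18, and 10 p53 targets rose rather than 9. With the preset correlation, 12 of 23 lists tested passed, 2 of them upwards and 10 downwards. With an estimated correlation 0 passed after adjustment (smallest camera adjusted p = 0.0663) and 8 had an unadjusted p under 0.05. Of the 35 ways to split the libraries into 4 and 4, the real one included, 8 called at least 12 lists.

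**Figure D3:**
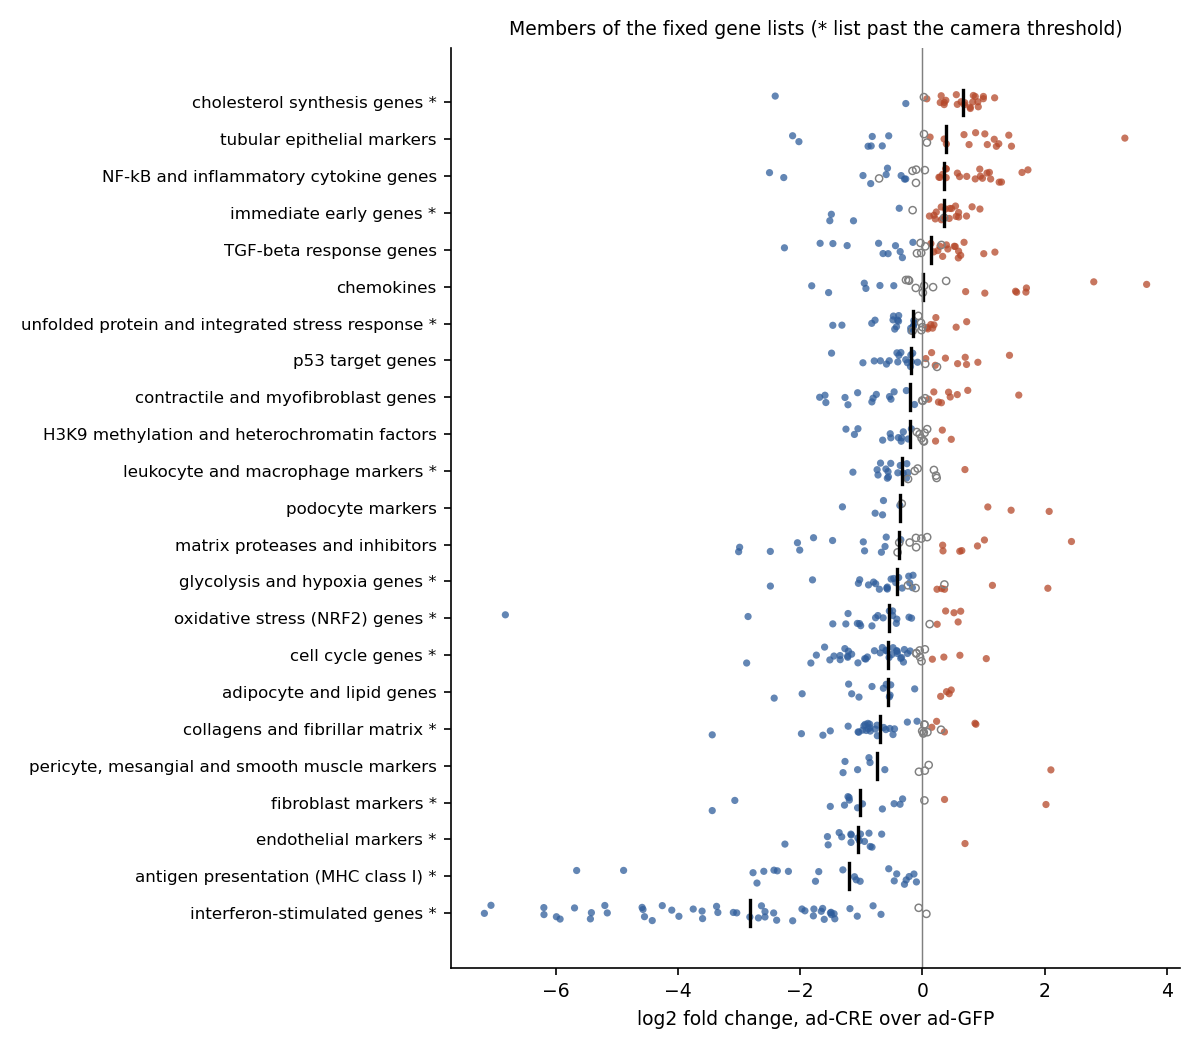
Log2 fold change (ad-CRE over ad-GFP) of every tested member of the 23 fixed lists tested, one point per gene, filled where the gene passed the threshold and open where it did not, with a black bar at the list's median. The median is −2.83 for interferon-stimulated genes, the lowest of the 23 lists, and 0.66 for cholesterol synthesis genes, the highest.

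Of 44 cell cycle genes tested, 34 fell, 4 rose and 6 did not pass (median −0.57, camera adjusted p = 4.19e-08, adjusted p = 0.0663 with an estimated correlation). Mcm6 and Mcm4, subunits of the replicative helicase, had log2 fold changes of −1.83 and −1.52, Rrm1, a subunit of ribonucleotide reductase, −1.45, and the S phase cyclin gene Ccne2 −2.88. Ccnd1, the G1 cyclin, rose by 0.61. Of 22 H3K9 methylation and heterochromatin factors, Suv39h1 among them, 12 fell, 3 rose and 7 did not pass. Dnmt1, the maintenance DNA methyltransferase, had −1.25, and its partners Uhrf1 and Hells had −1.06 and −1.11, whereas the H3K9 demethylase Kdm4a rose by 0.47 and Atrx by 0.32. The list did not pass (median −0.21, camera adjusted p = 0.0596, adjusted p = 0.298 with an estimated correlation). It passed in 10 of 19 alternative settings, among them DESeq2 statistics (cameraPR adjusted p = 0.0366) and fry, which does not compare a list with other genes. It also passed in the fits without ad-GFP replicate 1, ad-GFP replicate 2 or ad-CRE replicate 4 (camera adjusted p = 0.0485, 0.0494 and 0.0495). Of 28 p53 targets, 17 fell, 9 rose and 2 did not pass (median −0.19, camera adjusted p = 0.137), with −0.97 for the cell cycle inhibitor Cdkn1a and 0.91 for Ei24. Of 3 germline genes tested, Piwil2 fell (−1.15), while Tdrd1 and Brdt did not pass, with −0.42 (edgeR adjusted p = 0.136) and −0.09 (edgeR adjusted p = 0.81), and no set test was made. Without ad-CRE replicate 1, Tdrd1 passed at −0.67 (edgeR adjusted p = 0.0344).

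Matrix and fibroblast genes mostly fell, with exceptions among the most abundant transcripts. Of 38 genes for collagens and fibrillar matrix, 26 fell, 5 rose and 7 did not pass (median −0.69, camera adjusted p = 0.000343, adjusted p = 0.187 with an estimated correlation). Col1a1, a chain of type I collagen, went from 170 ± 8.36 to 59.7 ± 0.995 CPM (SD, n = 4; log2 fold change −1.51, edgeR adjusted p = 1.78e-25). Col12a1 had −1.05 and the collagen chaperone Serpinh1 −0.92. Fn1, encoding fibronectin and the most abundant transcript, rose by 0.36, and Thbs1, encoding thrombospondin 1, by 0.87. Fibroblast markers fell in 13 of 16 genes, 2 rose and 1 did not pass (median −1.02, camera adjusted p = 0.00324, adjusted p = 0.0663 with an estimated correlation), and 8 of the list's genes are held by other lists too. The list's median lay between −1.235 and −0.53 over the alternatives. Vim, encoding vimentin, had −1.22, the collagen receptor Ddr2 −3.07 and Cd34 −1.28. Beside these falls, 14 of 23 tubular epithelial markers rose and 7 fell (median 0.39, camera adjusted p = 0.0648) and 16 of 17 endothelial markers fell (median −1.06).

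The genes of contraction, TGF-β response and matrix turnover moved in both directions. Of 26 contractile and myofibroblast genes, 14 fell, 9 rose and 3 did not pass (median −0.20, camera adjusted p = 0.217, adjusted p = 0.532 with an estimated correlation). The list passed with DESeq2 statistics (cameraPR adjusted p = 0.0366). Tagln had −0.83 and Cnn1 −1.06, both smooth muscle cytoskeletal genes, while the myosin light chain kinase Mylk rose by 1.58 and the tropomyosin gene Tpm1 by 0.45. Of 31 TGF-β response genes, 15 rose, 11 fell and 5 did not pass, with a median of 0.14, a mean of −0.06 and a camera direction upwards (camera adjusted p = 0.591). Among them the receptor Tgfbr2 rose by 0.68, the ligand Tgfb3 by 1.0 and the matricellular gene Ccn1 by 1.19, whereas Il11 had −2.26. Ccn2, a connective tissue growth factor gene, did not pass (−0.02, edgeR adjusted p = 0.36), but did with scaling by total counts only (−0.05, edgeR adjusted p = 0.0334). Of 27 matrix proteases and inhibitors, 13 fell, 7 rose and 7 did not pass (median −0.38, camera adjusted p = 0.149). Over the alternatives this median lay between −0.42 and −0.11. Plau, encoding urokinase, rose from 285 ± 8.73 to 1544 ± 26.3 CPM (SD, n = 4; log2 fold change 2.44, edgeR adjusted p = 1.47e-34), Adam12 rose by 1.01, and the protease inhibitor Serpine2 and the gelatinase Mmp9 had −2.01 and −1.47.

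Cholesterol synthesis genes rose together. Of 24 tested, 21 rose, 2 fell and 1 did not pass (median 0.66, camera adjusted p = 1.44e-05, adjusted p = 0.0663 with an estimated correlation). Fdps, encoding farnesyl diphosphate synthase, rose by 1.0, from 111 ± 6.69 to 221 ± 10.4 CPM (SD, n = 4). Glycolysis and hypoxia genes fell in 20 of 28, with 5 that rose and 3 that did not pass (median −0.41, camera adjusted p = 0.000872, adjusted p = 0.0663 with an estimated correlation), among them Pfkp (−1.80), Ldha (−1.05), Pgk1 (−1.03) and the lactate exporter Slc16a3 (−2.49). Of 25 oxidative stress genes controlled by NRF2, 19 fell, 5 rose and 1 did not pass (median −0.54, camera adjusted p = 0.000288, adjusted p = 0.0663 with an estimated correlation), with −2.85 for Nqo1, −1.22 for the ferritin gene Fth1 and −1.47 for the cystine transporter Slc7a11. Of 16 adipocyte and lipid genes, 12 fell and 4 rose (median −0.57, camera adjusted p = 0.0744, adjusted p = 0.253 with an estimated correlation), with −2.43 for Pparg and 0.47 for Scd2. That list passed on the log2(FPKM + 1) scale (camera adjusted p = 0.0398) and the log2(FPKM + 0.1) scale (camera adjusted p = 0.0448).

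Of 30 genes of the unfolded protein and integrated stress responses, 17 fell, 8 rose and 5 did not pass (median −0.15, camera adjusted p = 0.0402, adjusted p = 0.177 with an estimated correlation). Atf5 had −1.32 and the chaperone Hspa5 −0.48. That list no longer passed without ad-CRE replicate 1 (camera adjusted p = 0.0576), without ad-CRE replicate 4 (camera adjusted p = 0.0534) or with no filter beyond 1 read (camera adjusted p = 0.0546). Immediate early genes rose in 18 of 24, with 4 that fell and 2 that did not pass (median 0.35, camera adjusted p = 0.012, adjusted p = 0.177 with an estimated correlation), among them Btg2 (0.72), Junb (0.59) and Fosl2 (0.44), with Klf4 at −1.52.

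Of the 5 marker lists of kidney cell types other than fibroblasts, the endothelial and leukocyte lists passed and the other 3 did not. Epithelial transcripts were abundant in all 8 libraries of this line given as fibroblasts: Krt8 and Cdh1 lay above Col1a1 in each of them. Mesenchymal transcripts were abundant too: Vim lay above Cdh1 in every library, and above Krt8 in each ad-GFP but below it in each ad-CRE library. Whether the cultures were fibroblast, epithelial or mixed was not determined here. Of 23 tubular epithelial markers, 14 rose, 7 fell and 2 did not pass (median 0.39). The keratin gene Krt8 rose from 745 ± 45.5 to 1983 ± 55.0 CPM and Cdh1, encoding E-cadherin, from 204 ± 9.57 to 484 ± 11.2 CPM (SD, n = 4), log2 fold changes of 1.41 and 1.25. Cldn4, a tight junction gene, rose by 1.46, and the injury marker Havcr1 had −2.02. The list did not pass (camera adjusted p = 0.0648, adjusted p = 0.356 with an estimated correlation). It passed in 8 of 19 alternative settings, among them DESeq2 statistics (cameraPR adjusted p = 1.1e-05), the fit without ad-GFP replicate 1 (camera adjusted p = 0.0485) and fry. Endothelial markers fell in 16 of 17, and 1 rose (median −1.06, camera adjusted p = 4.46e-05, adjusted p = 0.0663 with an estimated correlation). Emcn had −1.36, Cdh5 −1.06 and Pecam1 −1.03. The level of Pecam1 was only 27.2 ± 1.95 CPM in ad-GFP and 13.3 ± 0.613 CPM in ad-CRE (SD, n = 4). Camera compared the list with genes of every expression level, so a fall shared by weakly expressed genes in general was not told apart. Leukocyte and macrophage markers fell in 15 of 22, with 1 that rose and 6 that did not pass (median −0.34, camera adjusted p = 0.012, adjusted p = 0.356 with an estimated correlation), and Cd68 had −1.14 and Lyz2 −0.56. That list did not pass with DESeq2 statistics (cameraPR adjusted p = 0.0605). Of 10 pericyte, mesangial and smooth muscle markers, 6 fell, 1 rose and 3 did not pass (median −0.74, camera adjusted p = 0.137), with 2.10 for Notch3 and −1.06 for Pdgfrb. The median of this list lay between −0.99 and −0.19 over the alternatives. Of 9 podocyte markers, 5 fell, 3 rose and 1 did not pass, with a median of −0.37, a mean of 0.06 and a camera direction downwards (camera adjusted p = 0.68).

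The authors' deposited table holds its own comparison of the groups. It lists 9795 genes at an FDR under 0.05, 4771 higher and 5024 lower in ad-CRE. Of these, 9262 were also called here in the same direction and 62 in the opposite direction, 471 were not tested here, and 698 genes were called here and not in the authors' deposited table. The authors' directions are the signs of ratios of mean FPKM while those here come from counts, so unlike measures are compared. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.991 and a Spearman correlation of 0.986. In the authors' deposited table the log2 fold change was −0.37 for Suv39h1, 2.79 for Cxcl10 and −3.14 for Smarca4.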

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

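The counts of splits and the search for single libraries far from their group were fixed before their results were seen, and the tests of the explanations for Smarca4, for the interferon-stimulated genes and for the epithelial transcripts were chosen after them.

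The 10022 genes past the threshold were not matched by any other way of splitting the libraries. Of 35 splits into 4 and 4, 1 (the real one) called that many, and the highest of the others called 0 in edgeR, with at most 882 genes at an unadjusted p under 0.05. With 35 splits, 1 in 35 is the smallest share that this test can give. The count of genes thus speaks against a chance assignment of these 8 libraries but does not exclude it. Every other split mixes libraries of both groups, so few calls there would follow from any difference between the groups, whatever its cause. The labels do not say whether replicates were separate cultures, so a difference between 1 ad-GFP and 1 ad-CRE culture that arose by chance is not excluded. The count of lists is different: 8 of 35 splits called at least the 12 lists of the real one, and the highest of the others called 14, so chance is not excluded for that count by this test. The other 7 all kept 3 of the 4 libraries of each group together, while the 18 splits that put 2 libraries of each group on either side called at most 2 lists.

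Smarca4 fell 8.40-fold while Suv39h1, the gene the series names, kept 0.785 of its level. Loss of a stretch of chromosome 9 reaching well beyond Smarca4 would lower the genes around it. The 62 other tested genes within 1 Mb had a median log2 fold change of 0.0341 (95% interval −0.067 to 0.19), against such a loss. Single genes among them ranged from −2.89 to 2.49, and Dnmt1 and Cnn1, named above among the genes that fell, lie in this window. A loss confined to Smarca4 or a few neighbours would hardly move this median and was not tested. Of the other scalings of the counts, by DESeq2 size factors and by total counts, the lowest value for Suv39h1 was −0.376. Under neither was a much larger fall seen, but both are relative, so a change in RNA per cell would not show. That the ad-CRE cells carried a deleted Smarca4 allele rather than a Suv39h1 one cannot be told apart from a modest Suv39h1 knockdown with a secondary fall of Smarca4: 17.7% of genes of similar expression fell at least as much as Suv39h1 and 0.0391% at least as much as Smarca4, and gene totals do not show a missing exon. A biological effect of Cre on Suv39h1, the design's own explanation, stays open and would need reads over single exons.

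Interferon-stimulated genes fell while Cxcl10, itself inducible by interferon, rose. Fewer leukocytes would lower leukocyte markers as far, but their median was −0.34 (95% interval over genes −0.58 to −0.13) against −2.83 for the interferon-stimulated genes. The lowest of these markers had −1.14. The transcripts of 7 interferon receptor chains and kinases were not lower, with a median of 0.268 and 5 that rose. Reads on interferon ligand genes were too few to decide, 36 in ad-GFP and 46 in ad-CRE (ratio per total count 1.16, exact 95% interval 0.733 to 1.84), and Ifnb1 had 5 and 0. A difference in the response to the viruses, or an effect of the ad-CRE treatment on interferon signalling, may underlie the pattern, and neither was tested, since each virus goes with 1 group.

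Of 23 tubular epithelial markers, 14 rose and 7 fell, a list that did not pass (camera adjusted p = 0.0648), while most collagen and fibroblast genes fell. A larger share of tubular cells would raise their abundant transcripts alike, but of 18 abundant markers 12 rose and 4 fell, among the latter Havcr1 (−2.02), Wfdc2 (−0.84), Cdh16 (−0.66) and Lrp2 (−0.55). Loss of a small share of endothelial cells and leukocytes would hardly change abundant transcripts of the remaining cells, whether epithelial or fibroblast, yet 5 of 21 such genes changed by at least 1 log2 unit (Krt8, Krt18, Cldn4 and Spp1 upwards and Vim downwards). Mixtures of different kinds of tubular cell, or of epithelial cells and fibroblasts that both changed, were not tested and stay open. A change of state within the same cells, tied to the ad-CRE treatment, may account for the pattern and is only a hypothesis.

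In 14 of 290 groups of 4 values the highest or lowest library stood far from the other 3, where chance gives about 1 in 20, or 14.5. In ad-GFP replicate 4 these were Cxcl10 at 14.0 CPM (others 18.3 to 18.8), Prss22 at 19.6 CPM and Cdh5 at 37.9 CPM. In ad-GFP replicate 3 they were Npl at 4.09 CPM and Pkm at 1659 CPM, and in ad-GFP replicate 1 Tgfbr2 at 333.7 CPM. In ad-CRE replicate 1 they were Tpm1 at 2998 CPM, Fosl2 at 190.1 CPM and Synpo at 79.1 CPM, and in ad-CRE replicate 3 Emcn at 19.2 CPM. In ad-CRE replicate 4 they were Il11 at 14.0 CPM, Tgfbr2 at 504 CPM, Ptgs2 at 59.9 CPM and Cldn4 at 893 CPM.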

How the results depend on the processing

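Every alternative here was planned except those for Smarca4, Peg3, Zim1 and Usp29, which were added after their values were seen. Suv39h1 stayed below 0 and past the threshold in 17 alternatives (log2 fold change −0.40 to −0.32 when 1 library was left out) and so did Cxcl10 above 0 (2.72 to 2.84). The count of called genes was 9768 to 9983 when 1 library was left out, 9606 with DESeq2, 8366 with the stricter filter, which tested 10972 genes, 10765 with no filter, and 9268 and 9287 on the log2(FPKM + 1) and log2(FPKM + 0.1) scales. More genes fell than rose with total counts only (5287 against 4734), DESeq2 size factors (5032 against 4991), DESeq2 (4817 against 4789), no filter (5419 against 5346) and the FPKM scales (4991 against 4277 and 5004 against 4283). The numbers of the replicates did not pair the libraries (correlations of same-numbered deviations −0.053 to 0.065, and not every library correlated best with its own number), and the replicate block called 9963 genes. With the block the stress response list did not pass (camera adjusted p = 0.0527) and the adipocyte and lipid list did (0.0492). Requiring 1 log2 unit left 1955 genes (663 that rose and 1292 that fell) and 1850 shared with the authors' deposited table, by construction. Of the lists, 11 to 14 passed when 1 library was left out, 0 with an estimated correlation (8 at an unadjusted p under 0.05), and 23 with fry, directional or mixed, which does not compare a list with other genes. The podocyte list turned from down to up in the set test with DESeq2 (median −0.38) and fry (median −0.37), Tnfaip3 turned to −0.022 and −0.023 in the 2 FPKM fits, and Brdt, which did not pass, ranged from −0.32 to 0.14 when 1 library was left out, above 0 without ad-GFP replicate 4 and without ad-CRE replicate 1. The cause was not tested. Among single lists that kept their direction 388 values kept their call, 30 gained it and 17 lost it. The 2 values that turned direction, both of the podocyte list, were counted apart. The heterochromatin list passed without ad-GFP replicate 1 (camera adjusted p = 0.0485), ad-GFP replicate 2 (0.0494) or ad-CRE replicate 4 (0.0495), and the tubular list without ad-GFP replicate 1 (0.0485). Among named genes that kept their sign 2346 values kept their call, 2 gained it and 7, all of Plk2, lost it. The 4 values that turned sign, of Tnfaip3 and Brdt, were counted apart. Tnfaip3 lost its call on both FPKM scales (limma-trend adjusted p = 0.641 and 0.642). The FPKM scales shrink folds of low genes by construction: Cemip had 2.42 and Ddr2 −1.03 on the log2(FPKM + 1) scale, but 4.21 to 4.38 and −3.56 to −2.91 in counts when 1 library was left out.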

Other observations

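The pathway tests and the test of zinc finger genes were chosen after values were seen, whereas the bounds for the SWI/SNF subunits (apart from Smarca2) and for the neighbours of Peg3 were set before those values were seen.

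Among 323 pathways of the deposited annotation with 10 to 300 tested genes, camera called 17, 5 upwards and 12 downwards, and 0 with an estimated correlation (smallest adjusted p = 0.402). DNA replication genes fell in 30 of 36 (median −0.78, camera adjusted p = 1.02e-05, adjusted p = 0.402 with an estimated correlation), and mismatch repair genes in 16 of 23 (median −0.58, camera adjusted p = 0.0148, adjusted p = 0.402 with an estimated correlation). The broader cell cycle pathway was not called, with 59 of 122 genes that fell and 35 that rose (median −0.13, camera adjusted p = 0.196, adjusted p = 0.429 with an estimated correlation). Fanconi anemia pathway genes, which act in repair of DNA crosslinks, fell in 28 of 51 (median −0.36, camera adjusted p = 0.0326, adjusted p = 0.402 with an estimated correlation). Olfactory transduction genes fell in 39 of 65 and rose in 8 (median −0.65, camera adjusted p = 0.019, adjusted p = 0.402 with an estimated correlation). Ribosome genes rose by small amounts in 78 of 129 (median 0.11, camera adjusted p = 0.0148, adjusted p = 0.64 with an estimated correlation). Adherens junction genes rose in 42 of 68 (median 0.15, camera adjusted p = 0.019, adjusted p = 0.402 with an estimated correlation), with Cdh1 among those with the smallest p. Hippo signalling genes rose in 75 of 138 (median 0.15, camera adjusted p = 0.0418, adjusted p = 0.412 with an estimated correlation).

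The fall of Smarca4 was not shared by most other SWI/SNF subunits. Of 26 tested, 15 rose and 3 fell, with a median of 0.267 (95% interval −0.011 to 0.43), which argues against a general fall of the complex's transcripts. Arid1b rose by 0.71, Arid2 by 0.66 and Bicral by 1.16, and the other ATPase gene, Smarca2, did not pass (−0.02, edgeR adjusted p = 0.753). Those that fell were Dpf3 (−3.13, SE 0.574), Phf10 (−0.42, SE 0.031) and Dpf2 (−0.12, SE 0.036). The size of the fall of Dpf3 is thus far less certain than that of Smarca4 (SE 0.044).

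Less Suv39h1 might raise C2H2 zinc finger genes, many of which lie in clusters rich in H3K9 methylation. The 501 tested genes that the deposited annotation places in this family did not rise as a group, with a median of −0.0529 (95% interval −0.096 to −0.011), 151 that rose, 192 that fell and a camera p of 0.346. The interval treats the genes as independent. Suv39h1 kept 0.785 of its level and H3K9 methylation was not measured, so the test cannot tell what a loss of the mark would do to these genes.

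The imprinted genes Peg3, Zim1 and Usp29, neighbours on chromosome 7 and singled out after their values were seen, fell together, with log2 fold changes of −2.51, −3.22 and −2.49. Peg3 went from 838 ± 13.0 to 147 ± 7.81 CPM (SD, n = 4). The other 13 tested genes within 1 Mb had a median of 0.33 (95% interval −0.069 to 1.16), against a loss that reached over most of that window. A loss confined to Peg3, Zim1 and Usp29 was not tested, since these genes were left out of the median. In mouse tissues Peg3 and Usp29 are known as paternally and Zim1 as maternally expressed, and which copy was expressed in these cells was not analysed here.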
